A study of Mus musculus with 8 samples.

How the data were processed

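Single-nucleus multiome libraries (RNA and ATAC of the same nuclei) were made from nuclei of sorted tdTomato-positive cells of mouse alveolarspheres, per the labels' protocols. The labels name 8 samples in 4 groups of 2. The authors deposited raw UMI counts per gene and nucleus (32285 genes, 7224 nuclei) and raw ATAC counts per peak and nucleus (116068 peaks with a median width of 906 bp) as 2 pooled matrices with gene names, peak positions and barcodes. Per the submitters' processing notes, Cell Ranger 6.0.1, Seurat 4.3.0 and Signac 1.10.0 and the builds GRCm38 and mm10 were used, with no role or order given for each. The peak caller and the filter on nuclei before deposit are not given in the sources used here. Nuclei in the deposited matrix had at least 81 UMIs and at most 19.9% mitochondrial counts. Files that list multiplexing oligos name other samples and were not used here.

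Barcodes carry 4 prefixes, called libraries A to D in sorted order of the prefix. No label ties a prefix to a sample, so nuclei were not assigned to Sox9-Cre or Cre and the planned tests between groups (edgeR, sums per class, peaks and gene lists) were not run. The pooled matrix counts as 1 sample. Values per library are given one by one or as a range, with no mean and no test. Comparisons of a cluster with other nuclei were also made inside single libraries.

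Nuclei were kept with at least 500 UMIs, at least 300 genes and under 20% mitochondrial counts, which removed 25. Scrublet (in scanpy) was run per library and marked 15 nuclei (0.208%), which were removed. At so low a share the caller was treated as not having worked. Whether doublets were removed before deposit is not given in the sources used here, so doublets can remain. An alternative left out the 5% of nuclei with the highest scores (273). Counts were scaled to 10000, log-transformed and reduced to 2000 variable genes, without Sox9, Cre and tdTomato, then to 30 principal components, 15 neighbours and Leiden clusters at resolution 0.8 with seed 0, giving 14 clusters. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used.

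Cell type markers and the other gene lists (26 lists, 385 genes with 379 in the matrix) were fixed before the data were examined. The lists cover ATII, ATI, transitional, airway secretory, goblet, basal, ciliated, neuroendocrine, gut and stomach, mesenchymal, endothelial, immune, mesothelial, cell cycle, distal tip progenitor, cartilage, epithelial-mesenchymal transition, lipid synthesis, p53 and senescence, interferon, YAP, BMP and TGF-beta, WNT, Notch, MHC class II and RNA quality genes. The rule for names was set after the clusters were seen. A marker supported a cluster when it had a UMI in at least 5% of its nuclei and was at least 1.5-fold higher than elsewhere. A cluster took the name of the list, out of 13, with the highest share of supporting markers, if at least 3 markers and 30% of the list supported it and at least 3 were among its top 50 genes by fold with a UMI in at least 20% of nuclei. Cluster 7 had 10 of 23 transitional markers supporting and 2 in the top 50, and stayed unnamed by this threshold. So did cluster 10, with 11 supporting and 0 in the top 50, and cluster 11, with 13 and 1. A cluster's own markers are not results.

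Levels are UMIs of a gene per 10000 UMIs, summed over the nuclei of a class, with exact Poisson 95% intervals. Shares have exact Clopper-Pearson 95% intervals. A count of 0 was given the limit of 3 counts. Folds compare a class with all other nuclei; a count below 3 was set to 3, and a list member was tested if the gene had at least 30 UMIs in all. A member counted as higher from 2-fold on if it also had more than 3 UMIs in the class, and as lower from 2-fold on. In small classes members set to 3 counts can raise a list's median without being counted as higher. The median log2 fold of a list was set beside 10000 random lists of the same size matched in 20 bins of mean level, as a description. No p-value was computed, since nuclei are not replicates. The text names Sox9, the 5 genes outside a class's list with the highest fold among genes with a UMI in at least 20% of its nuclei, and up to 4 members of each list by level or spread between classes; other members named in the report, such as Vim, Zeb2, Hey1, Col2a1, Col9a3 and Nkd1, were chosen after their values were seen. The values of a few genes that this rule takes in are not reported here.

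For ATAC, peaks overlapping a gene or the 2000 bp on either side were summed per class, per 10000 counts in peaks. Gene positions came from a RefSeq gene table of GRCm38.p6, which gives gene ends without strand or exons, so this window replaced the planned window around transcription start sites. Of the genes in the matrix 26652 (82.6%) had a position, as had 374 listed genes. The build was checked: 27.8% of gene ends lay in a peak as listed, against 5.32% to 6.51% after shifts of the positions. The accessibility of a list used genes with at least 200 counts and a fold of 1.25. Chromatin clusters for the closing tests came from the ATAC counts alone (108200 peaks, 30 components after leaving out the first, which followed depth). The components used still correlated with log depth, by up to 0.3645.

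The fold calculation was tested on simulated counts with known changes. At the size of the ATI-like class (12788 genes) 50 of 50 genes changed 2-fold, 4-fold and 0.25-fold were recovered, and 48 of 50 changed 0.5-fold. At the size of cluster 10 (10120 genes) 50 of 50 were recovered at each of these folds. A 2-fold or 0.5-fold change counted as recovered within 1.5 times its true value, and a 4-fold or 0.25-fold change from 2-fold on. Only genes with at least 30 UMIs expected in the class were simulated, with Poisson counts and no differences between nuclei or libraries. Folds from fewer UMIs in a class, or that differ between libraries, were thus not covered. Alternatives covered the clustering resolution, components, filters on nuclei, doublets, libraries, thinning to 1000 UMIs, weighting by nucleus, and the window and counting of peaks.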

Results

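The data came from mouse alveolarspheres, small three-dimensional cultures grown in serum-free medium without feeder cells from type II alveolar epithelial cells (ATII cells), the surfactant-making cells of the lung that can give rise to flat type I (ATI) cells. On day 9 the cultures were infected with an adeno-associated virus of serotype 9 that carried Cre recombinase alone (Cre) or Cre together with the transcription factor Sox9 (Sox9-Cre). They were then kept for 4 days in a medium that drives ATII cells toward ATI cells. Cells with the red reporter tdTomato were sorted, and RNA and open chromatin (ATAC) were read from the same single nuclei. The labels list 8 samples, 2 per group for Sox9-Cre RNA, Cre RNA, Sox9-Cre ATAC and Cre ATAC, and the question they pose is how extra Sox9 acts on the lineage plasticity of ATII cells. The counts came as 1 matrix for RNA and 1 for ATAC, in which the nuclei carry 4 library prefixes that no label ties to a sample. The libraries are therefore called A, B, C and D, no Sox9-Cre against Cre comparison was made, and the pooled matrix was described as 1 sample without replicates. Which nuclei came from young and which from old mice was likewise not assigned.

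After filtering, 7184 nuclei remained, 1260 in library A, 760 in B, 3236 in C and 1928 in D. The RNA totals were 13618399, 9862297, 39803023 and 25073946 UMIs (unique molecular identifiers, which count captured RNA molecules) in that order, with medians per nucleus of 9802, 11599.5, 11090 and 11728. The ATAC medians were 4405, 3776, 9609 and 13991.5 counts in peaks per nucleus, and 12.2% of nuclei had under 1000. All intervals below are 95% intervals and cover counting error only, not differences between cultures or animals.

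Most nuclei fell along the ATII to ATI axis. ATII-like nuclei (2538, clusters 2, 3 and 8) made up 35.3% (exact binomial interval 34.2 to 36.4), ATI-like nuclei (1699, clusters 0 and 5) 23.6% (22.7 to 24.6), and transitional-like nuclei (1454, clusters 1 and 6), with the keratin and claudin genes of cells between both types, 20.2% (19.3 to 21.2). Airway secretory-like nuclei (148) were 2.06% (1.74 to 2.42) and ciliated-like nuclei (22) 0.306% (0.192 to 0.463). The remaining nuclei stayed in unnamed clusters. Cluster 7 held 8.41%, cluster 10 4.75% (4.27 to 5.26), cluster 4 3.58%, cluster 11 1.29% and cluster 9 0.390%. The shares depended on the clustering. The 3 main classes together held 79.2% of nuclei, but 60.02% with at least 1000 UMIs per nucleus and 84.03% at resolution 0.4. Nuclei thus also moved between these classes and unnamed clusters. The filter at 1000 UMIs left out 31 nuclei, and keeping the 15 doublet calls in gave 69.17%. Small changes in the nuclei used therefore moved the shares of these classes beyond their counting intervals. Over the alternatives the ATII-like share ranged from 21.3% to 36.5%, the ATI-like share from 13.9% to 26.3%, the transitional-like share from 19.4% to 36.0%, the airway secretory-like share from 1.26% to 3.73%, the ciliated-like share from 0.152% to 0.371% and the share of cluster 10 from 3.19% to 7.74%. No ciliated-like class was found at resolution 0.4, with at least 1000 UMIs or with pathway genes left out of the clustering, so its range covers the 8 other alternatives. Leaving out library D gave the lowest values for airway secretory-like and ciliated-like nuclei, and without library C cluster 11 held 0.203%.

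In libraries A, B, C and D, in that order, the ATII-like share was 29.9%, 31.3%, 38.8% and 34.5%, the ATI-like share 31.7%, 29.9%, 21.0% and 20.5%, and the transitional-like share 24.4%, 23.0%, 17.3% and 21.4%. Cluster 7, which a threshold set after the data were seen kept out of the transitional-like class, took 8.73%, 10.5%, 7.48% and 8.92%. Cluster 10 held 0 of 1260 nuclei of library A, which allows a share of up to 0.238%, 0 of 760 in B (up to 0.395%), 215 in C (6.64%) and 126 in D (6.54%). These limits hold for the main clustering only, since at resolution 0.4 the matching cluster held 10 nuclei of A and 11 of B. Airway secretory-like nuclei numbered 0, 0, 66 and 82, ciliated-like nuclei 0, 0, 8 and 14, and nuclei of cluster 11 0, 0, 85 and 8 (2.63% of C and 0.415% of D).

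**Figure D1:**
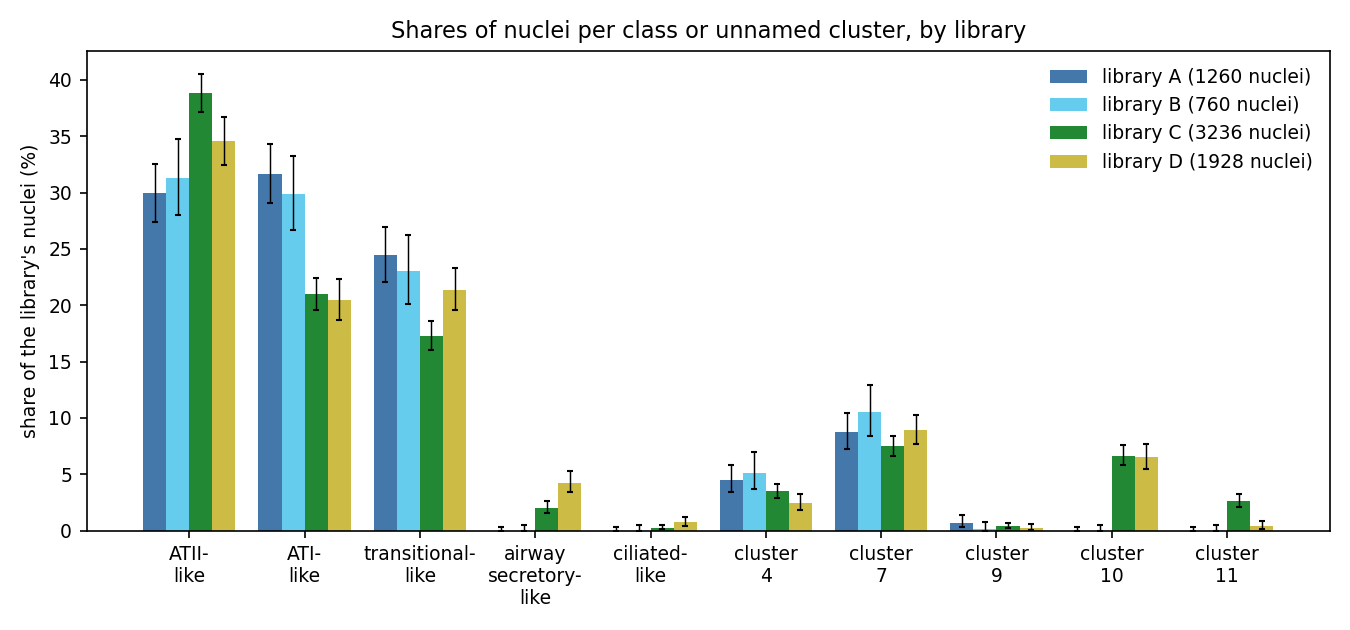
Share of each library's nuclei (percent, bars from 0) in each named class or unnamed cluster, for libraries A to D, with exact binomial 95% intervals as error bars. ATII-like nuclei took between 29.9% and 38.8% of each library, and cluster 10 between 0% and 6.64%.

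ATII-like nuclei were rich in transcripts of lipid synthesis and of antigen presentation. Of the 22 lipid synthesis genes, 11 were at least 2-fold higher per UMI than in all other nuclei and 1 at least 2-fold lower. Scd1, which desaturates fatty acids, stood at 61.6 UMIs per 10000 against 7.27 elsewhere (8.48-fold, and 8.21- to 10.2-fold within the 4 libraries). Elovl1, an elongase, was 8.27-fold higher and Fasn, the fatty acid synthase, 7.004-fold higher, while Elovl6 was lower (0.309-fold, from 70 UMIs). The median log2 fold of the list was 1.01, while 95% of random lists matched on level lay between -0.34 and 0.06. Of 7 tested MHC class II genes, 6 were at least 2-fold higher, among them H2-Aa (6.74-fold), H2-Ab1 (5.17-fold) and Cd74 (14.5 against 4.87 per 10000, 2.99-fold). These genes took part in the clustering. With every pathway gene left out of it, 13 lipid synthesis genes and 7 MHC class II genes were at least 2-fold higher.

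Targets of YAP, a regulator that responds to cell stretch, and interferon genes were low in ATII-like nuclei. Of 14 YAP targets 8 were at least 2-fold lower and 0 higher (median log2 fold -1.32, matched random lists -0.41 to 0.12). Of 15 tested interferon genes 12 were lower and 0 higher (median -2.02, random lists -0.51 to 0.17). The other nuclei include cluster 9, which held 50.95 interferon UMIs per 10000 and adds to this difference. The summed list stood at 1.05 in ATII-like, 1.84 in ATI-like, 2.22 in transitional-like nuclei and 1.68 in cluster 7. Id2, a BMP target, was 3.74-fold higher at 3.82 per 10000, and 2 of 12 BMP and TGF-beta targets were 2-fold higher and 3 lower. Of 8 tested WNT targets 2 were higher, Nkd1 (12.6-fold, 8.22- to 18.0-fold within libraries), which also ranked among the leading genes of the class, and Axin2 (2.60-fold). Of 18 tested genes of the distal tip progenitor list, which mark the growing tips of the fetal lung, 4 were higher and 3 lower. The 5 genes outside the marker list with the highest folds were Adam19 (51.9-fold), Tspan11 (34.0-fold), Ly6c2 (19.0-fold), Slco4c1 (16.4-fold) and the cytokine gene Il33 (16.1-fold). They describe the cluster and were not tested. Of the ATII list itself 20 of 22 genes were higher, by definition of the class, with Sftpc, which encodes surfactant protein C, at 872 per 10000. Sftpc also stood at 24.0 in airway secretory-like and 10.7 in ciliated-like nuclei, cells that should lack it, so levels near these can be free RNA.

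ATI-like nuclei carried few of the listed pathways at a higher level. Sparc, a secreted matrix protein gene, was at 17.3 per 10000 against 7.99 elsewhere (2.16-fold), while Fn1 (0.141-fold) and Vim (0.159-fold) were lower, so that of 12 tested epithelial-mesenchymal transition genes 3 were 2-fold higher and 5 lower. In the p53 and senescence list, Cdkn2b, an inhibitor of the cell cycle, was 2.34-fold higher (2.05- to 2.49-fold within libraries), Gdf15 was lower (0.152-fold) and 13 of 16 genes lay in between. Of 12 tested BMP and TGF-beta targets 7 were lower and 0 higher, and of 22 lipid synthesis genes 4 were lower and 0 higher. Of 5 tested Notch targets 0 were higher and 2 lower, with the most abundant of them, Hes1, at 3.72 per 10000, close to its level in cluster 7 (3.72) and in airway secretory-like nuclei (3.68). The leading genes outside the ATI list included Pmp22 (7.46-fold), Phactr1 (7.23-fold), Sema3a (5.85-fold) and C330002G04Rik (5.34-fold). Of the 25 ATI markers 17 were 2-fold higher, by definition of the class. Ager, the classic ATI receptor gene, stood at 58.6 per 10000 here and at 17.4 in ATII-like nuclei.

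Targets of YAP were higher in transitional-like nuclei than in all other nuclei together, which include the low ATII-like class. The summed list stood at 19.6 per 10000 here and at 8.88 in ATII-like, 15.5 in ATI-like nuclei and 11.6 in cluster 7. It was also high in cluster 4 (20.6), cluster 11 (19.5) and cluster 10 (17.4), so it was not particular to this class. Of 14 YAP targets 6 were at least 2-fold higher and 0 lower, among them Ankrd1 (0.415 against 0.0346 per 10000, 11.97-fold), Ccn2 (6.37-fold, 4.24- to 15.6-fold within libraries), Nt5e (3.02-fold) and Ccn1 (2.26-fold). With pathway genes left out of the clustering the count was 6. Of 16 genes of the p53 and senescence list 2 were higher, with Gdf15 (3.10-fold) among them, and 0 lower; the list's median log2 fold was 0.53, with 95% of matched random lists between -0.26 and 0.27. Cdkn1a, the p21 gene, is shared with the transitional list. Stress genes of the RNA quality list differed in both directions in this class: Hspa1a was 3.83-fold and Hspa1b 3.57-fold higher, Atf3 2.05-fold higher and Fos lower (0.303-fold). Of 7 tested immune genes 4 were higher and 0 lower (median log2 fold 1.06, random lists -1.004 to 0.60), at low levels: Cd68 at 0.0946 per 10000 (2.09-fold), Itgam (17.3-fold, from 39 UMIs), Mrc1 (4.41-fold, from 21) and Cd79a (2.89-fold, from 21), named after their values were seen. The leading genes outside the marker list were Tpm2 (8.65-fold), 9930111J21Rik2 (7.56-fold), Pdlim7 (7.51-fold), Ccn2 and Ptgs2 (5.45-fold). Of the 23 transitional markers 20 were higher by definition.

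Most lead genes of these classes were also more accessible in them. Accessibility was taken as ATAC counts in peaks over a gene and 2 kb on either side, per 10000 counts in peaks. Of the 96 ATII-like lead genes with peaks among the top 100, 91 were more accessible in ATII-like nuclei than elsewhere, with a median of 1.27-fold. For ATI-like nuclei it was 86 of 91 genes at 1.17-fold, and for transitional-like nuclei 82 of 98 at 1.13-fold. Single genes differed more: Sftpb 1.68-fold (1.59 to 1.78), Lamp3 1.64-fold, Scd1 1.48-fold, H2-Aa 1.46-fold and Sftpc 1.45-fold in ATII-like nuclei, Ager 1.78-fold (1.64 to 1.93) in ATI-like nuclei, and Ankrd1 2.04-fold and Cldn4 1.89-fold (1.74 to 2.04) in transitional-like nuclei. With a window of 10 kb the fold at Ager was 1.18. Whole lists differed less: Scd1 was the 1 of 22 lipid synthesis genes past the fold set for accessibility in ATII-like nuclei (median 1.075-fold), where 5 of 8 MHC class II genes passed it (median 1.29-fold), and Ankrd1 the 1 of 14 YAP targets in transitional-like nuclei (median 1.07-fold).

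Sox9 RNA was concentrated in cluster 10. The 341 nuclei of this cluster held 52.5% of all Sox9 UMIs and stood at 7.87 Sox9 UMIs per 10000 (exact Poisson interval 7.61 to 8.14), which was 20.75-fold (19.8 to 21.8) above all other nuclei. Within library C the level was 8.10 and the fold over the other nuclei of the library 14.8, and within D they were 7.49 and 15.8. Without library C the pooled fold was 30.5. A Sox9 UMI was seen in 91.2% of its nuclei (87.7 to 94.0) and, with each nucleus thinned to 1000 UMIs, in 40.5% (35.2 to 45.9). In airway secretory-like nuclei, with a median of 14215 UMIs against 11540 in cluster 10, these shares were 16.2% and 0.680%. The levels in the other classes were 0.435 per 10000 in ATII-like, 0.384 in transitional-like, 0.203 in ATI-like, 0.147 in airway secretory-like and 0.261 in ciliated-like nuclei, and in clusters 4, 7, 9 and 11 they were 0.233, 0.578, 0.665 and 0.602. These pooled levels mix libraries that differ in Sox9, so no order is read from them: within C and D the level was 0.904 and 0.696 in cluster 7 and 0.621 and 0.405 in cluster 11. Without library C it was 0.249 in transitional-like and 0.132 in ATI-like nuclei. In cluster 9, 2 nuclei of library D held 16 of the 24 Sox9 UMIs, and in cluster 4 library C gave 36 of the 40. Sox9 was left out of the genes used for clustering. Its RNA and ATAC counts can come from the chromosomal gene or from the viral Sox9 sequence, and the counts as used here do not separate them. Genes named Cre or tdTomato were not among the genes of the RNA matrix used here.

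Sox9 lies on chromosome 11 from 112782210 to 112787757 (GRCm38), and 3 peaks overlap it, at 112782331 to 112783169, 112783490 to 112784356 and 112784666 to 112785551. Together they were 3.76-fold (3.50 to 4.03) more accessible in cluster 10 than in the other nuclei, 2.88-fold within library C and 3.45-fold within D, and 2.60-fold when each peak was counted as 0 or 1 per nucleus. In cluster 11 the fold was 4.88 (4.31 to 5.51), with a Sox9 RNA level of 0.602 per 10000. Of its 93 nuclei 85 came from library C, where the fold was 4.16 (3.66 to 4.71), while the 8 nuclei of library D held 4 counts in these peaks, at 0.522-fold (0.142 to 1.34). Within libraries C and D the folds were 0.673 and 0.769 in ATI-like, 0.841 and 0.787 in transitional-like and 0.749 and 0.804 in ATII-like nuclei. In A and B, with 9 to 34 counts per class, the intervals of these folds included 1.

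**Figure D2:**
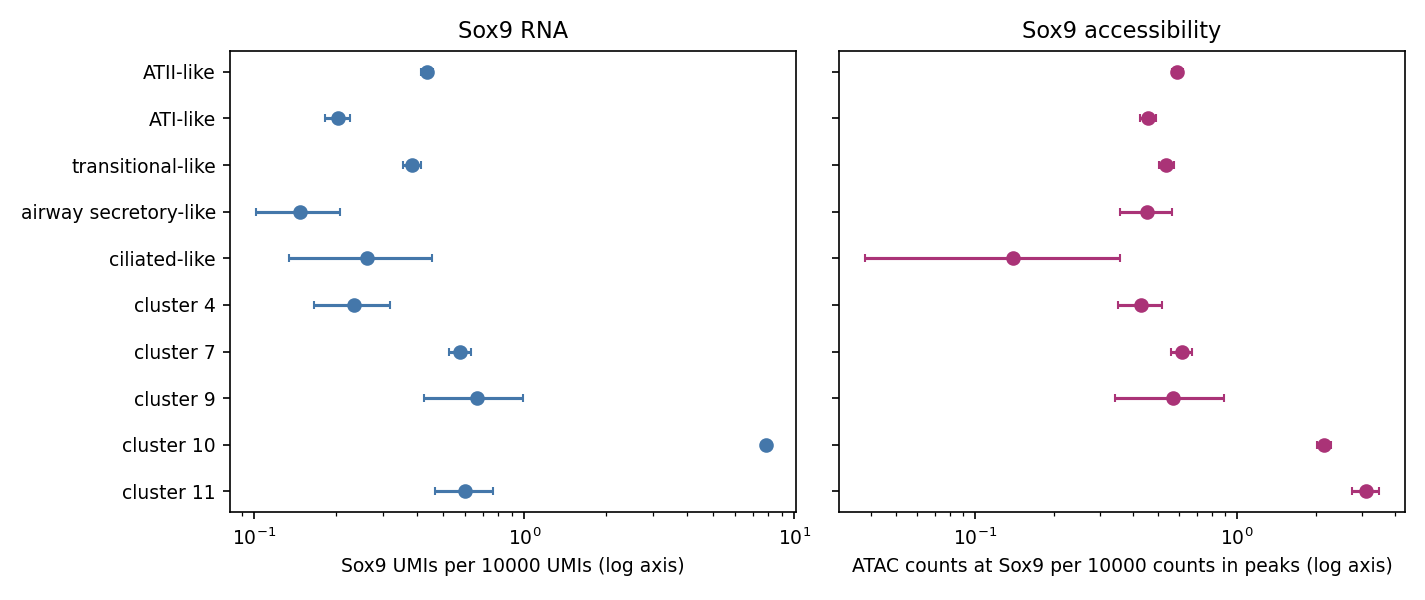
Sox9 UMIs per 10000 UMIs (left) and ATAC counts in the 3 Sox9 peaks per 10000 counts in peaks (right) for each class or unnamed cluster, pooled over the libraries, on log axes with exact Poisson 95% intervals. Cluster 10 has the highest RNA level, 7.87; the accessibility of cluster 11 comes from library C at 3.49 per 10000, against 0.3505 from 4 counts in D.

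Cluster 10 carried part of the cartilage programme that Sox9 drives in skeletal cells. Of 13 tested genes of that list 8 were at least 2-fold higher with more than 3 UMIs and 2 lower, with a median log2 fold of 4.02, where 95% of matched random lists lay between -0.17 and 0.54. Sox6, a partner of Sox9 in cartilage, was at 3.18 per 10000 (3.01 to 3.35) against 0.165 elsewhere (19.3-fold; 17.4-fold within library C and 12.2-fold within D). The collagen genes Col9a3 (0.711 per 10000, 79.3-fold), Col27a1 (0.723, 49.9-fold), Col2a1 (0.287, 43.7-fold) and Col11a2 (0.229, 14.2-fold) and the sulfotransferase gene Chst11 (0.184, 55.0-fold) were also higher. The other 2 of the 8 rested on few nuclei: Col11a1 had 37 UMIs in 1.76% of the nuclei, 36 of them in library C, and Comp 26 UMIs in 0.880%. The fold of Comp was 70.3 within library D. Within C it was 2.21 only because a count below 3 was set to 3, so no rise was shown there. Comp was also less accessible in cluster 10 (0.787-fold, 0.651 to 0.944). Acan, Matn1 and Hapln1, abundant in mature cartilage, had 0 UMIs, which allows up to 0.00673 per 10000. Matn4 (0.157-fold) and Fgfr3 (0.357-fold; 0.246-fold within C and 0.588-fold within D) were lower, Sox5 was at 0.718-fold, and Matn3, at 2.01-fold from 3 UMIs (0.391 to 6.51), was not counted. The count stayed at 8 with pathway genes left out of the clustering.

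Accessibility passed the fold set for it upward at 10 and downward at 4 of 19 members of the list, with a median of 1.252-fold. Col9a3 (chromosome 2, 180598102 to 180622192) was 9.05-fold (7.48 to 10.9) more accessible, 6.82-fold within library C and 10.4-fold within D, and 2.14-fold with a 10 kb window, which takes in a peak 8161 bp away that did not differ (1.02-fold). Col11a2 was 3.70-fold, Sox6 (chromosome 7, 115470872 to 116040776) 2.70-fold over 35 peaks, Chst11 2.22-fold, Col2a1 1.42-fold and Col27a1 1.34-fold higher. The largest difference among the Sox6 peaks, at 115679592 to 115680526, was 27.3-fold, but 9 of the 35 were lower in cluster 10, down to 0.351-fold at 115788924 to 115789940, from 4 counts. The annotation used gives gene ends but no exons, so peaks were not placed in exons or introns.

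**Figure D3:**
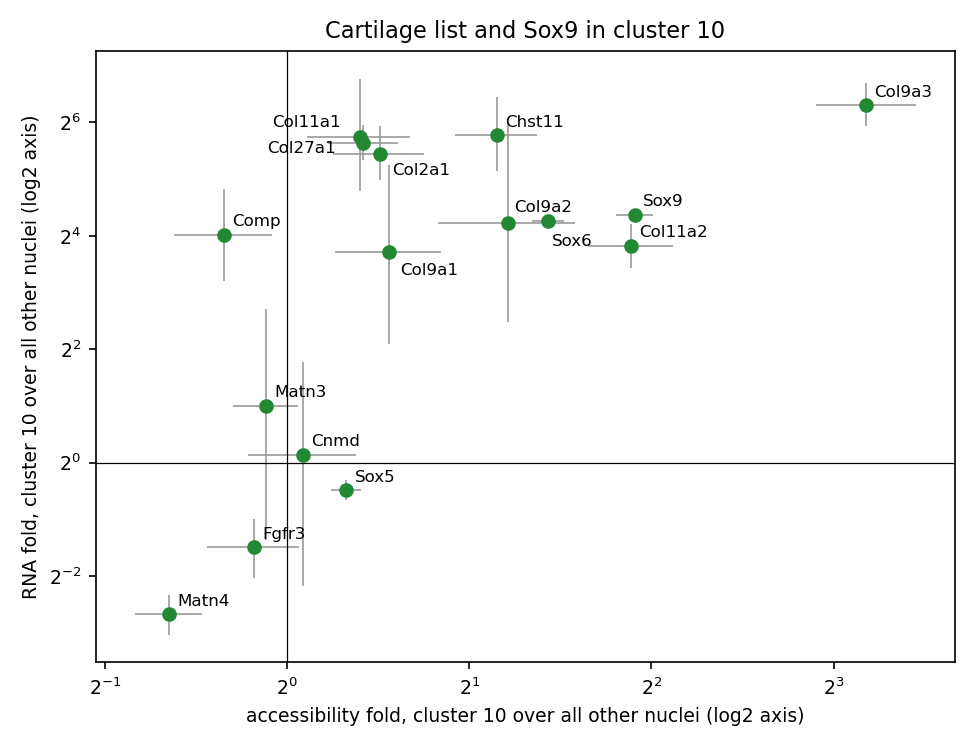
RNA fold against accessibility fold of the cartilage list and Sox9 in cluster 10 over all other nuclei (both axes log2), with 95% counting intervals. Each point is a gene with 3 or more UMIs both in cluster 10 and in the other nuclei and at least 1 peak; Col9a3 has the highest folds on both axes, 79.3 for RNA and 9.05 for accessibility.

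Alveolar identity genes were low in cluster 10. Of 22 ATII genes 21 were at least 2-fold lower and 0 higher, with Sftpc at 29.4 per 10000, close to the 24.0 of airway secretory-like nuclei, and of 25 ATI genes 15 were lower and 0 higher. The other nuclei hold the ATII-like class, and against them 21 ATII genes were also lower in transitional-like nuclei and in cluster 7, 19 in cluster 11 and 18 in ATI-like nuclei, while ATI genes were lower at 3 in transitional-like nuclei and 6 in cluster 7. The ATII count was 13 at resolution 0.4 and with pathway genes left out. The transitional list was mostly in between, with 4 of 23 higher, namely Tubb6 (2.71-fold), Lgals3 (2.56-fold), Anxa1 (2.16-fold) and Cldn4 (2.02-fold). Accessibility passed its fold downward at 9 and upward at 1 (Chil1, 1.49-fold) of 21 ATII genes, with a median of 0.825-fold, Sftpb at 0.487-fold (0.406 to 0.580) and Sftpc at 0.505-fold. Of 25 ATI genes it did so downward at 8 and upward at 1 (Igfbp2, 1.82-fold), with a median of 0.865-fold and Ager at 0.407-fold. Lipid synthesis had 5 of 22 genes lower and 0 higher, and MHC class II 6 of 7 lower.

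Of 12 tested epithelial-mesenchymal transition genes 5 were higher in cluster 10 and 2 lower. Vim, the intermediate filament of mesenchymal cells, was at 0.667 per 10000 (29.3-fold), the repressor gene Zeb2 at 0.164 (28.5-fold) and Fn1 at 1.57 (4.53-fold), while Sparc was lower (0.247-fold). Accessibility passed its fold upward at 3 of 14 members, Vim (2.05-fold, 1.77 to 2.36), Zeb2 (1.86-fold, 1.70 to 2.04) and Mmp2 (1.26-fold), and downward at Sparc (0.697-fold) and Itgb3 (0.759-fold), and the list's median of 1.01-fold lay within the range of random lists. YAP targets had 6 of 14 higher and 0 lower, with Amotl1 2.73-fold and Ccn2 2.91-fold. Ccn2 differed between the libraries, at 1.26 per 10000 and 1.865-fold within C and at 3.60 and 4.32-fold within D. BMP and TGF-beta targets had 3 of 12 higher and 1 lower, and the distal tip list 2 of 18 higher, Sox9 and Hmga2, and 5 lower, with Shh (0.112-fold), Bmp4 (0.192-fold) and Foxp2 (0.360-fold) among the lower. Of 5 tested Notch targets Hey1 was higher (34.1-fold, from 49 UMIs). The summed Notch list, made up mostly of Hes1, was lower, at 1.56 per 10000 against 2.65 over all nuclei. This was its lowest level among the classes and clusters. Of the p53 and senescence list 0 of 16 were higher. The RNA quality list had 1 of 14 higher and 0 lower. The genes outside the lists that led the cluster were Lama4 (133-fold), a laminin gene, Wfdc18 (79.8-fold) and Itgb8 (67.2-fold), with Lama4 6.85-fold and Wfdc18 30.04-fold more accessible. Ctse, a stomach protease gene of the gut and stomach epithelium list, was at 0.972 per 10000 (50.2-fold) and was the 1 higher of 3 tested members, with 1 lower.

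The other clusters differed in their leading genes. Airway secretory-like nuclei held 806 UMIs per 10000 of the airway secretory list, with Scgb3a1 at 279 and Bpifa1 at 127, and ciliated-like nuclei held 68.4 of the ciliated list, with Foxj1, the regulator of motile cilia, at 8.18. Of the lead genes with peaks, 81 of 85 and 76 of 84 were more accessible, with medians of 1.82-fold (95% of matched random lists 0.905 to 1.05) and 1.795-fold (random lists 1.11 to 1.39). Outside the lists their leading genes included Slco1a5, Klk10, Atp6v1b1 and Tacr1, and in ciliated-like nuclei Gm19935, Zfp474, 1700024G13Rik, Elmod1 and Sntn. Cluster 9 (28 nuclei from all 4 libraries) was defined by interferon genes: 14 of 15 tested interferon genes were higher, with Ifit3 at 9.90, Isg15 at 9.40 and Rsad2 at 2.72 per 10000. It was not found as a cluster with 15 principal components or with pathway genes left out of the clustering. Cluster 11 was led by Mgarp, Bst1, Loxl2, Serpinb9b and Slc16a3, and held Msln, a mesothelial list gene, at 8.42 per 10000 and Ndrg1 at 1.00. At resolution 0.4 its closest match was the airway secretory-like cluster (29.9% of the nuclei of both shared). Cluster 7 was led by Gsta2 (14.5-fold), Cyp2s1 (5.02-fold), Cbr3 (4.49-fold), Sprr1a (4.22-fold) and Htra4 (4.19-fold). It was not stable, since in the 7 re-clusterings the closest match shared 18.2% to 57.1% of nuclei and was transitional-like in 2 and ATI-like in 1. Cluster 4 had a median of 6056 UMIs and Malat1, a nuclear RNA, at 959 per 10000 against 499 over all nuclei, which sets it apart by RNA content, and its lead genes were about as accessible as random lists (52 of 90 higher, median 1.01-fold, random lists 0.989 to 1.03).

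Other cell types were scarce. Over all nuclei the immune list summed to 0.498 UMIs per 10000 with Lyn at 0.391, the endothelial list to 0.121, the mesenchymal list to 0.119, the neuroendocrine list to 0.104 with Uchl1 at 0.0917, the goblet list to 0.168, the basal list to 0.0537, the gut and stomach list to 0.110 and the mesothelial list to 0.685, of which Msln was 0.609. The basal list was highest in airway secretory-like nuclei (0.795), where 2 of 5 tested genes were at least 2-fold higher. In cluster 11 it stood at 0.709, with 1 of 5 higher. The goblet list was also highest in airway secretory-like nuclei, at 2.58 per 10000, with 7 of 8 tested genes at least 2-fold higher. The cell cycle list summed to 1.72 per 10000, with Pcna at 0.640, and was highest in the 22 ciliated-like nuclei (7.96).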

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

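No paired analysis was possible because no label or file ties the nuclei to the labelled replicates. For the same reason these variants of the Sox9-Cre against Cre tests were not run: the replicate block, DESeq2, no filter on low counts, leaving out each replicate, thinning and clustering for the tests within classes. Leaving out the highest doublet scores, leaving pathway genes out of the clustering, folds within a library, and leaving out a library for levels and accessibility were chosen after seeing the data. For 18 main results, 192 alternative values under 16 settings were computed. Of these, 121 stayed within the counting interval or within 1.5 times a count, and 71 moved. Only the folds, of Sox9 RNA and of accessibility, could be labelled reversed, and 0 of them were. Shares, levels and counts of list members could not be. The counts of higher lipid synthesis (10 to 14), MHC class II (6 to 7), YAP (5 to 7) and cartilage genes (6 to 8) stayed within 1.5 times the main value in every alternative run. The cause of the moves below was not tested, except where the setting itself removes nuclei of a library or adds peaks.

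The ATII-like share (35.3%) was 23.6% at resolution 0.4, 26.2% at 1.2, 23.3% with at least 1000 UMIs, 32.0% with doublet calls kept, 21.3% with 15 components, 23.3% without the 5% highest doublet scores and 22.3% with pathway genes left out of the clustering. Under the same settings except resolution 0.4 the ATI-like share (23.6%) was 22.4%, 13.9%, 15.4%, 17.2%, 26.3% and 18.8%. The transitional-like share (20.2%) was 36.0% at resolution 0.4 and then 26.55%, 22.8%, 21.8%, 22.4%, 24.6% and 22.7%. Cluster 10 (4.75%) was matched to 7.74%, 3.605%, 7.55%, 7.49%, 6.72%, 4.17% and 7.06% of nuclei. The airway secretory-like share (2.06%) was 3.73% at resolution 0.4, where its 268 nuclei were also the closest match of cluster 11. No ciliated-like class was found at resolution 0.4, with at least 1000 UMIs or with pathway genes left out, which gave no value.

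The Sox9 level of cluster 10 (7.87 per 10000) was 5.67 at resolution 0.4, 8.72 at 1.2, 5.84 with at least 1000 UMIs, 5.83 with doublet calls kept, 8.26 without the highest doublet scores, 6.29 with pathway genes left out, 7.185 thinned to 1000 UMIs and 7.20 as a mean over nuclei. Its fold over the other nuclei (20.75) was 17.4 at resolution 0.4, 17.8 with at least 1000 UMIs, 17.55 with doublet calls kept, 19.4 with pathway genes left out, 17.7 thinned and 17.9 as a mean over nuclei. The count of ATII genes 2-fold lower in it (21) was 13 at resolution 0.4 and 13 with pathway genes left out. With a 10 kb window the accessibility fold was 2.14 at Col9a3 (9.05), 1.75 at Sftpc (1.45), 1.18 at Ager (1.78) and 1.72 at Cldn4 (1.89); with peaks as 0 or 1 it was 2.60 at Sox9 (3.76) and 1.70 at Cldn4.

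Leaving out each library in turn gave ranges of 32.45% to 36.5% for the ATII-like share, 21.9% to 25.9% for ATI-like, 19.35% to 22.7% for transitional-like, 1.26% to 2.498% for airway secretory-like, 0.152% to 0.371% for ciliated-like and 3.19% to 5.76% for cluster 10. The Sox9 level of cluster 10 ranged from 7.49 to 8.10, its fold from 17.5 to 30.5, and the accessibility fold from 3.31 to 4.87 at Sox9 and from 8.32 to 11.95 at Col9a3. The number of nuclei limits the small groups, ciliated-like nuclei (22) and cluster 9 (28), and depth the ATAC values, since 878 nuclei had under 1000 counts in peaks.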

Other observations

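The tests of nuclei numbers, of cartilage cells and of doublets were chosen after their results were seen; the tests on chromatin clusters, on Sox9 UMIs in ATII-like nuclei and on peaks outside Sox9 were written before their results were seen. Sox9 RNA stood at 0.0148 UMIs per 10000 in library A, 0.0144 in B, 1.08 in C and 0.941 in D. The values of A and B lie close together and apart from those of C and D, which also lie close together. ATAC counts in the 3 Sox9 peaks were 0.107, 0.105, 0.899 and 0.670 per 10000 in the same order, and in the 3 peaks outside the gene within 100 kb 0.0559, 0.0442, 0.0876 and 0.0675. The peak at 112784666 to 112785551 stood at 0.0151, 0.0147, 0.390 and 0.268, and the peak at 112782331 to 112783169 at 0.0663, 0.0736, 0.311 and 0.245. Outside cluster 10, ATII-like nuclei held 0.0195, 0.0203, 0.583 and 0.534 Sox9 UMIs per 10000, and ATI-like nuclei 0.00520, 0 (which allows up to 0.0116), 0.310 and 0.325.

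Clusters made from chromatin alone held most of the nuclei of cluster 10 together. One of 12 chromatin clusters held 571 nuclei, 324 of them from cluster 10, and 4.61% of ATII-like and 4.06% of transitional-like nuclei also lay in it. Another held 93.9% of airway secretory-like nuclei.

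Clusters 10 and 12 (airway secretory-like) held 0 nuclei of libraries A and B, as did cluster 11, where 16.3 and 9.84 would be expected, and the ciliated-like cluster (3.86 and 2.33). The lower number of nuclei in these libraries does not account for this in clusters 10 and 12, since at the clusters' shares at least 15.66 nuclei would be expected in each library and cluster. A split made by the RNA clustering alone does not match the chromatin data, where 95.01% of cluster 10 lay in one chromatin cluster with 0% of its nuclei from libraries A and B, against 28.1% of all nuclei. In 4 of the 7 RNA re-clusterings the matching cluster held a few nuclei of A and B, at most 10 and 11 of 556 at resolution 0.4, and in the other 3 it held 0. In the main clustering, clusters 10 and 12 lay only in libraries C and D. These libraries also held more Sox9 RNA, 1.08 and 0.941 UMIs per 10000 against 0.0148 in A and 0.0144 in B. A batch difference between libraries, which also differ in ATAC depth, stays open. No biological explanation was tested, because no library is tied to a group or to the age of the mice. The labels name 2 Sox9-Cre and 2 Cre samples for RNA, and Sox9 RNA also split the libraries 2 against 2. Such a split would be seen if C and D were the Sox9-Cre libraries, but it was not used to assign them.

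Cartilage genes were high in cluster 10. Cartilage cells among the sorted nuclei would lack epithelial transcripts, but the median ratio of 12 epithelial genes to the other nuclei was 1.296 (0.539 to 2.78, Epcam 2.78), with 0 UMIs of Acan, Matn1 and Hapln1 together. Doublets would hold more RNA, but the median UMIs were 1.06 times those of the other nuclei in library C and 0.959 times in D. For the hypothesis that the cartilage list goes with Sox9 UMIs in ATII-like nuclei, the ratio of the summed list between nuclei with and without a Sox9 UMI was 1.01 in library C and 0.9345 in D, which decides nothing, because Matn4 and Sox5, not raised in cluster 10, made up 89.4% and 87.6% of the sum. In values looked at afterwards the 8 list genes raised in cluster 10 had ratios of 2.15 (1.63 to 2.84) and 3.53 (2.498 to 5.03). The rise was not limited to ATII-like nuclei. In C and D the ratios were 1.84 and 1.84 in ATI-like nuclei, 2.42 and 3.83 in transitional-like nuclei and 2.09 and 1.84 in cluster 7, with intervals above 1. The 8 genes were picked from cluster 10, however, and a Sox9 UMI can be free RNA. A Sox9 UMI was also seen in 16.2% of airway secretory-like nuclei, but whether it was free RNA or their own was not tested. A link, free RNA and nuclei placed in the wrong cluster all stay open.

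Accessibility at Sox9 was high in clusters 10 and 11, where DNA of the vector, counted at the chromosomal gene, is a candidate source. In cluster 10 peaks outside the gene, which the Sox9 coding sequence does not hold, were also higher than in other nuclei. Against the other nuclei of the same library the fold was 4.61 in C (3.53 to 5.97) and 3.49 in D (2.42 to 4.95). These outer peaks do not show where the counts in the gene's own peaks came from, so vector DNA stays open for those. In cluster 11 of library C the gene's peaks were 4.16-fold higher while the outer peaks were at 0.728-fold (0.235 to 1.72), from 5 counts, and in its 8 nuclei of library D the gene's peaks were at 0.522-fold from 4 counts, which is too few to decide. Vector DNA and an opened gene cannot be told apart there.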
